A study of Mus musculus with 4 samples.

How the data were processed

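Total RNA was isolated from embryonic day 13.5 neuroretina with a QIAGEN RNeasy kit, depleted of ribosomal RNA with RiboMinus, labelled with biotin by the Affymetrix whole-transcript sense assay and hybridised to arrays, per the labels' protocols. There were 4 arrays, 2 labelled with loxP-flanked Lhx2 alleles (control) and 2 labelled with the same alleles and a Cre transgene (labelled knockout). Groups and replicate numbers were taken from the sample titles. Nothing in the labels says whether the replicates came from separate animals, litters or pools, so p-values measure only the spread between these arrays, which may be technical. On deposited values that spread was pooled over genes of like signal, so SEs and p-values do not reflect a gene's own replicates.

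The deposited values were log2 signals per transcript cluster. RMA (a background correction, quantile normalization and summary of probe signals), the software Partek and the genome build mm9 are named in the submitters' processing notes, without versions or parameters. The deposited log2 values were not on a common scale, since the array medians differed by more than the group difference, so a quantile normalization over the transcript clusters listed is not what these values show, and whether a later step moved them is not given in the sources used here. Scanner signals were not used here, and genomic positions of transcript clusters were not used here.

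Gene names came from a platform annotation table. Of 112205 transcript clusters, 25513 had 1 gene symbol, 2290 had several and 84402 were unnamed here; clusters with several symbols named no gene. Entrez identifiers of 24917 clusters matched the GRCm38.p6 RefSeq gene table, and 0 symbols changed. Of 20252 genes, 3104 had several probe sets, and the probe set with the highest mean over the 4 arrays stood for the gene. Among 84 genes named by the rule, 12 had several probe sets, and in 8 of them (A230054N11Rik, Ddr2, Gcnt4, Cldn1, Etv5, Eomes, Smad9 and Tyr) a probe set differed from the one used by over 1 log2 unit or in sign. No dim genes were left out. Of the 99 named genes with a call, 32 (24 rises and 8 falls) had every signal of the dimmer group below the 75th percentile of all transcript clusters on its array, so their differences compare a signal with one not told from background.

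Genes were tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with an intensity trend) on the deposited values, with genotype as the only term, a two-sided test and Benjamini-Hochberg adjustment over 20252 genes at an adjusted p of 0.05. "Rose" and "fell" are used of genes that passed this test. Of 28 gene lists, 27 were tested with limma's camera at a preset inter-gene correlation of 0.01, adjusted over the 27, and sex-linked genes were given as values only. Of the 27 lists, 1 is not reported here. Because array levels follow the replicate number, differences within the replicate 1 arrays and within the replicate 2 arrays are given beside the pooled values of most lists that passed and of some genes. The test, the lists, the rule for named genes and most alternatives were chosen before the data were examined. That rule takes Lhx2; the 12 largest rises and 12 largest falls among genes past the threshold whose groups do not overlap; and from each list the up to 4 passing members of smallest p, or the 2 of smallest p where none passes. A further 27 genes, including Isl1, Prdm13, Nr2f2, Birc5, Lgr5, Mitf, Aldh1a1, Aldh1a2, Fgfr2, Fgfr3, Atoh7, Tbr1, Wnt8b and most of those named with gene families or with a further list, were chosen after their values were seen. Rps18 and Rpl32l, named with the ribosomal protein family, were chosen in the same way but stand outside the counts of named genes.

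The gene test was tried on simulated data in which 200 of 20252 genes were changed. Levels were those of the 4 arrays, and spreads were drawn from genes of like signal. Noise was independent between arrays, so the simulation lacks the gene-specific structure by replicate number in the real arrays (same-numbered deviations correlated at 0.479 across genes). Its false shares also depend on the number of changed genes, and are not estimates for the real calls. On deposited values 36.0% of 239 calls were false, and 4, 49, 50 and 50 of 50 genes changed by 1, 2, 3 and 4 log2 units were recovered. After quantile normalization 2.36% of 127 calls were false, with 11, 32, 42 and 39 of 50 recovered, and after median centring 3.52% of 142 calls were false, with 16, 33, 46 and 42 recovered. At an adjusted p of 0.10 after quantile normalization, 6.88% of 160 calls were false. The adjusted p on deposited values therefore did not hold its stated error rate in the simulation.

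Alternatives covered filters on dim genes at the 25th percentile and at the median of level, quantile normalization, median centring, the variance prior, array weights, the rule for several probe sets, thresholds, the replicate number as a term, each array left out, an estimated inter-gene correlation and limma's fry. With 1 array left in a group, that array is assumed to vary like the other group. A background correction was not run, since it needs scanner signals.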

Results

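Gene expression was measured in the neuroretina, the neural layer of the developing eye, of CD-1 mouse embryos at embryonic day 13.5. The series title names genes under the control of Lhx2 in early retinal progenitors as its subject, and Lhx2 is a LIM-homeodomain transcription factor needed for eye development. The 2 control arrays came from embryos carrying loxP-flanked Lhx2 alleles. The other 2 arrays were labelled as the same alleles with a transgene that drives Cre recombinase in retinal progenitors, and are called the labelled knockout arrays here. Each array gave log2 signals for 112205 transcript clusters, from which 20252 genes were tested. The median log2 signal over all transcript clusters was 2.97 and 3.53 in control replicates 1 and 2, and 2.85 and 3.46 in labelled knockout replicates 1 and 2, so both replicate 2 arrays lay above the replicate 1 arrays. Across genes, which are not independent replicates, Pearson's r was 0.978 between the control arrays, 0.967 between the labelled knockout arrays and between 0.947 and 0.966 across genotypes. With 2 arrays per group, the number of arrays limits the precision of every value.

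Lhx2 itself, represented by 1 transcript cluster (6876532), had log2 signals of 6.36 and 6.49 in the control arrays and 6.38 and 6.50 in the labelled knockout arrays. Its log2 difference, labelled knockout minus control, was 0.02 (SE 0.35, approximate 95% interval -0.68 to 0.71, limma adjusted p = 1.00). The difference was 0.02 within the replicate 1 arrays and 0.01 within the replicate 2 arrays. Which exons the probes of this transcript cluster cover is not given in the sources used here, and a probe outside the deleted part does not report a deletion. The Lhx2 signal therefore does not check the genotype labels, and every direction given here rests on those labels.

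The comparison of labelled knockout with control arrays asked which genes differed with the labelled genotype. Only the labelled knockout group carries the Cre transgene, so an effect of the transgene cannot be told apart from loss of Lhx2. The 12 largest rises were led by Sim1, a transcription factor of hypothalamic neurons (transcript cluster 6767762), with a log2 signal of 3.28 ± 0.18 (SD, n = 2) in control and 8.37 ± 1.04 in labelled knockout arrays. The Sim1 signal was 33.9-fold higher, a log2 difference of 5.08 (SE 0.37), with a difference of 4.47 within the replicate 1 arrays and 5.70 within the replicate 2 arrays. The LIM-homeodomain genes Lhx5, Lhx1 and Lhx9 rose by 4.16, 3.56 and 3.50 on the log2 scale, and Otp, another hypothalamic transcription factor, rose by 3.75. Fezf1, a forebrain zinc-finger factor, rose by 4.11, Rspo3, a secreted enhancer of Wnt signalling, by 4.05, and the ligand gene Wnt7b by 3.54. The remaining rises were A230054N11Rik (3.97), the neuronal membrane protein gene Slitrk1 (3.62), Mlc1 (3.48) and the collagen receptor gene Ddr2 (3.46). Ddr2 differed by 5.36 within the replicate 1 arrays and by 1.55 within the replicate 2 arrays.

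Among the 12 largest falls, the glycosyltransferase gene Gcnt4 went from 8.22 ± 0.00 (SD, n = 2) in control to 3.74 ± 0.58 in labelled knockout arrays, 22.3-fold lower with a log2 difference of -4.48 (SE 0.36). Six6, a homeobox gene of the eye field, went from 8.46 ± 0.43 to 4.77 ± 0.32 and was 12.9-fold lower (log2 difference -3.69, SE 0.35), with differences of -3.61 and -3.76 within the replicate 1 and replicate 2 arrays. The growth factor gene Fgf15 fell from 10.05 ± 0.18 to 6.53 ± 0.11, a log2 difference of -3.52. Log2 differences were -3.48 for Dio3, which encodes a deiodinase that inactivates thyroid hormone, -3.34 for Foxn4, a forkhead factor of amacrine and horizontal cell specification, and -3.28 for the Wnt receptor gene Fzd5. Cldn1 (-3.12), the ETS factor gene Etv5 (-3.05), the T-box gene Tbx3 (-2.90), Nr0b1 (-2.81), Crhbp (-2.80) and Fgf3 (-2.79) completed these falls. For 9 of the 12 rises, Sim1 among them, both control signals lay below the 75th percentile of all transcript clusters on their arrays (4.06 and 4.52), as did both labelled knockout signals for 4 of the 12 falls against 3.98 and 4.52. Folds of these genes compare a signal with one not told from background, and the ranks are of signal differences. Across these 24 genes the SE of the log2 difference lay between 0.35 and 0.47. On deposited values limma set this SE from genes of like signal, not from a gene's own replicates. Ddr2, with an SD of 2.53 in the labelled knockout arrays, had an SE of 0.36, and of 1.36 after quantile normalization. Probe sets of A230054N11Rik, Ddr2, Gcnt4, Cldn1 and Etv5 disagreed by more than 1 log2 unit, and Cldn1 ranged from -3.12 to -0.79 across its 2 probe sets.

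**Figure D1:**
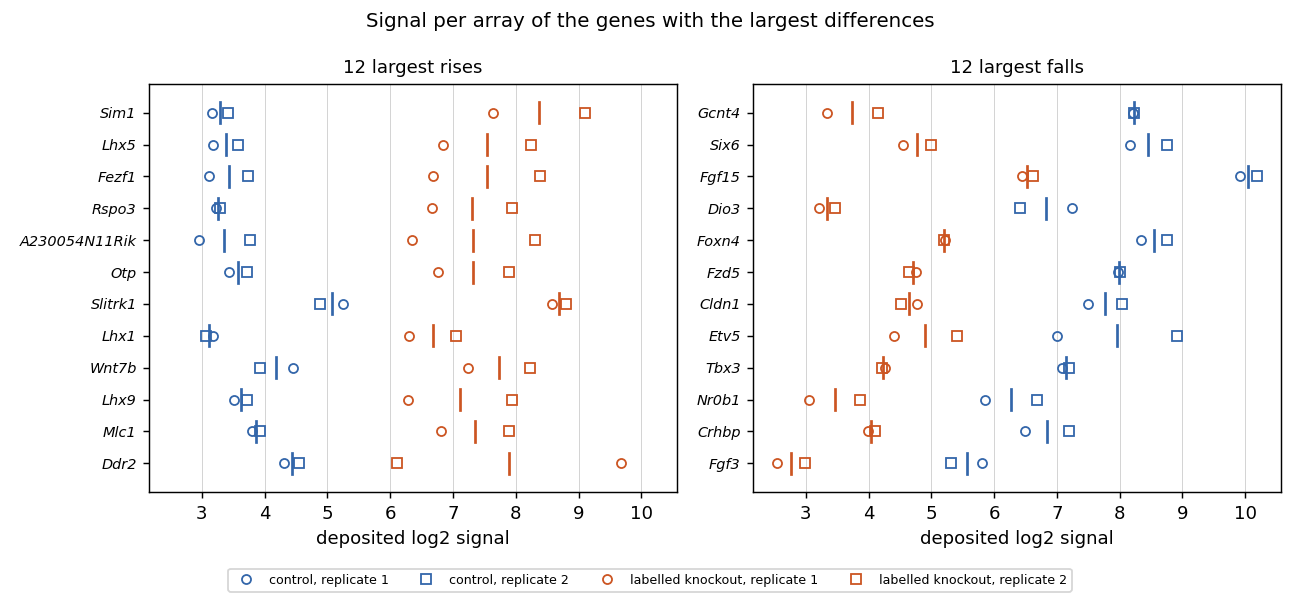
Deposited log2 signal (horizontal axis) of the 12 genes with the largest rises and the 12 with the largest falls in each of the 4 arrays, with circles for replicate 1, squares for replicate 2 and vertical bars for the group means. In all 24 genes the control and labelled knockout arrays do not overlap, and the labelled knockout arrays of Ddr2 lie furthest apart.

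In all, 415 of 20252 genes passed limma's adjusted p of 0.05 on the deposited log2 values, 257 higher and 158 lower in the labelled knockout arrays. Each of the 415 differed at least 2-fold. Within the replicate 1 arrays and within the replicate 2 arrays alike, 411 of them differed in the same direction, and 380 differed at least 1.5-fold in both, made up of 222 of the 257 rises and 158 of the 158 falls. The 415 were chosen on the mean of these same 2 differences. Their size and the agreement by replicate number are therefore partly built in, and are not a replication. This count depends on the scale of the arrays. In simulated data with the same array levels 36.0% of calls were false, a share that need not hold for these calls. Limma called 0 genes after quantile normalization at an adjusted p of 0.05 (2318 at an unadjusted p under 0.05, against 1012.6 expected by chance). There, 86 genes passed an adjusted p of 0.10, 40 higher and 46 lower, and with each array centred on its median 118 passed an adjusted p of 0.05, 52 higher and 66 lower. With the replicate number as a term limma called 0 genes at an adjusted p of 0.05 (3513 at an unadjusted p under 0.05) and 415 at 0.10, 160 higher and 255 lower. Of the 24 genes with the largest differences, 22 passed an adjusted p of 0.05 after median centring (all but Ddr2 and Etv5). After quantile normalization 19 of them passed an adjusted p of 0.10, and adjusted p ran from 0.0919 to 0.439 for the rises and from 0.0878 to 0.176 for the falls. With 1 array left out in turn, fewer genes were called. The median difference over all genes, -0.06 with all arrays, became -0.30 without control replicate 1 and 0.19 without control replicate 2. It became 0.20 without labelled knockout replicate 1 and -0.33 without labelled knockout replicate 2. Calls and list values in those fits carry this shift, since array levels follow the replicate number. In each of these fits, 21 of the 24 genes were called (all but Ddr2, Fgf3 and Nr0b1).

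Genes of retinal progenitor identity fell as a group. Of 22 measured members of this list, 5 fell and 1 rose (9 and 2 adjusted over the list alone). The median log2 difference was -0.77 (camera adjusted p = 2.38e-17, adjusted p = 0.522 with an estimated correlation). Beside Six6 and Fgf15, the falls were in Rax (-2.21), a homeobox gene required for eye formation, the cyclin gene Ccnd1 (-1.76) and Cdon (-1.29), while Nr2f2, an orphan nuclear receptor gene, rose 2.83-fold. Neurogenic progenitor genes also fell, with 6 of 23 members lower and 0 higher (7 and 1 adjusted over the list alone). The median was -0.48 (camera adjusted p = 8.05e-10, adjusted p = 0.522 with an estimated correlation). They included Foxn4, the Notch ligand gene Dll4 (-1.85), Neurod4 (-1.67), Gadd45a (-1.61) and Atoh7 (-1.73), the basic helix-loop-helix factor needed for retinal ganglion cells. The list medians within the replicate 1 and replicate 2 arrays were -0.65 and -0.92 for progenitor genes, and -0.77 and -0.39 for neurogenic genes. With labelled knockout replicate 1 left out, 3 progenitor and 2 neurogenic genes fell, 1 of each rose, and the list medians were -0.64 and -0.43. Over all 4 arrays the medians of periocular mesenchyme, vascular and retinal pigment epithelium genes were 1.40, 0.63 and 0.42. Within the replicate 2 arrays, where progenitor genes fell more and neurogenic genes less, those medians were 0.37, 0.22 and 0.08.

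Cell cycle genes shifted downward almost throughout. Of 39 measured members, 38 lay below 0 and the median log2 difference was -0.98, with -0.79 within the replicate 1 arrays and -1.13 within the replicate 2 arrays (camera adjusted p = 9.85e-28, adjusted p = 0.522 with an estimated correlation). Over all genes tested, 5 members fell and 0 rose: Ccnd1, Cdk6 (-1.51), the mitotic kinase gene Aurkb (-1.23), the S-phase regulator gene E2f1 (-1.23) and Birc5 (-1.21). Adjusted over the list alone, 27 fell and 1 rose. Without labelled knockout replicate 1, 0 members passed the gene threshold, while the median was -0.86 and the camera adjusted p was 2.75e-29. The fall stands beside medians of 1.40 for periocular mesenchyme, 0.63 for vascular and 0.42 for pigment epithelium genes over all 4 arrays. Within the replicate 1 arrays those medians were 2.60, 0.88 and 0.99, and within the replicate 2 arrays 0.37, 0.22 and 0.08. The larger cell cycle fall, in replicate 2, thus did not go with the larger rises of these lists. Muscle and ectoderm medians were also larger in replicate 1. Other rises were larger in replicate 2, with medians of 2.77 and 4.66 by replicate number for the 7 forebrain genes that rose, and 0.37 and 0.44 for macrophage and microglia genes.

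Fibroblast growth factor genes and their MAPK feedback targets fell, with 4 of 18 lower and 2 higher (5 and 2 adjusted over the list alone). The median was -0.44, or -0.31 and -0.55 within the replicate 1 and replicate 2 arrays (camera adjusted p = 8.99e-09, adjusted p = 0.522 with an estimated correlation). The falls were the ligand genes Fgf15, Fgf3 and Fgf9 (-1.78) and the transcription factor gene Etv5, and the rises were the receptor genes Fgfr2 (1.65, or 2.10 and 1.19 by replicate number) and Fgfr3 (1.64). The list median was -0.67, with 3 falls and 0 rises, without labelled knockout replicate 1. Of 21 genes that pattern the retina along its dorsoventral and nasotemporal axes, 5 fell and 2 rose (7 and 2 adjusted over the list alone). The median was -0.40, or -0.40 and -0.29 within the replicate 1 and replicate 2 arrays (camera adjusted p = 3.32e-05, adjusted p = 0.522 with an estimated correlation). The T-box genes Tbx3, Tbx2 (-1.69) and Tbx5 (-1.46), which mark dorsal retina, the retinoic acid hydroxylase gene Cyp26a1 (-2.31) and the retinaldehyde dehydrogenase gene Aldh1a1 (-1.37) fell. Bmp4 (mean signal 3.90 in control, 5.50 in labelled knockout) and Aldh1a2 (1.57) rose, the latter by 2.68 within the replicate 1 arrays and 0.45 within the replicate 2 arrays. The patterning median was -0.19 without labelled knockout replicate 1, beside 0.20 over all genes. Both the FGF and the patterning values come from arrays with medians of 1.40 for mesenchyme, 0.63 for vascular and 0.42 for pigment epithelium genes. Within the replicate 2 arrays, where the FGF fall was larger and the patterning fall smaller, those medians were 0.37, 0.22 and 0.08.

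Genes of the differentiating retinal cell types moved both ways. Photoreceptor precursor genes fell, with 2 of 19 lower and 0 higher (3 and 1 adjusted over the list alone). The median was -0.31, or -0.44 and -0.16 within the replicate 1 and replicate 2 arrays (camera adjusted p = 7.96e-05, adjusted p = 0.620 with an estimated correlation), and the members that fell were the photoreceptor factors Crx (-2.47) and Prdm1 (-2.43). Without labelled knockout replicate 1 the photoreceptor median was 0.06 and the mean -0.12, against a mean of -0.50 over all arrays. The median over all genes was 0.20 in that fit and -0.06 over all arrays. Mesenchyme, vascular and pigment epithelium medians in the same 4 arrays were 1.40, 0.63 and 0.42, or 0.37, 0.22 and 0.08 within the replicate 2 arrays. Of 29 retinal ganglion cell genes, 2 rose and 3 fell (3 and 3 adjusted over the list alone). The list did not pass (median 0.18, camera adjusted p = 0.381). Without labelled knockout replicate 1 its median was 0.56, beside 0.20 over all genes. Its changed members were Eomes (2.39) and Nrn1 (1.67), which rose, and Dlx2 (-2.33), Dlx1 (3.99-fold lower) and Isl1 (-1.27), which fell. The 3 probe sets of Eomes ranged from -0.20 to 2.39. Of 20 amacrine and horizontal cell genes, 2 rose (Lhx1 and Calb1, 2.16) and 3 fell (Foxn4, the GABA synthesis gene Gad2, -2.54, and Prdm13, -1.80), or 4 and 3 adjusted over the list alone. This list did not pass (median 0.17, camera adjusted p = 0.941), but it passed downward with all probe sets (camera adjusted p = 0.00798). Of 21 genes associated with Muller glia, the nuclear factor genes Nfib (1.95) and Nfix (1.53) and the retinoid binding protein gene Rlbp1 rose. Id1 (-1.31) fell, and adjusted over the list alone 5 rose and 4 fell. Rlbp1 (mean signal 3.67 in control, 5.17 in labelled knockout) also stands in the list of retinal pigment epithelium genes. The Muller glia list did not pass (camera adjusted p = 0.187), and its median of -0.08 and mean of 0.15 differed in sign.

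Genes of optic stalk and forebrain included Sim1, the largest pooled rise of any gene. Of 21 measured members, 7 rose and 2 fell (8 and 2 adjusted over the list alone). The camera adjusted p was 2.46e-25 (adjusted p = 0.522 with an estimated correlation). Sim1, Lhx5, Rspo3, Lhx9 and Eomes rose, as did Tbr1 (3.40), a cortical and thalamic eminence factor, and Wnt8b (2.85), while Dlx1 and Dlx2 fell. The median over the whole list was 0.24, or 0.48 and 0.18 within the replicate 1 and replicate 2 arrays, since 12 members did not pass. Without labelled knockout replicate 1 the list median was 0.43, beside 0.20 over all genes. The 7 rising members had a median of 2.77 within the replicate 1 arrays and 4.66 within the replicate 2 arrays, opposite in order to periocular mesenchyme genes, whose medians were 2.60 and 0.37 in the same arrays. Wnt8b differed by 1.03 within the replicate 1 arrays and 4.67 within the replicate 2 arrays.

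Wnt pathway genes and targets rose, with 6 of 23 higher and 2 lower (8 and 4 adjusted over the list alone). Camera gave an adjusted p of 0.000956 (adjusted p = 0.585 with an estimated correlation). The rises included Apcdd1 (2.69) and Axin2 (2.22), both feedback inhibitors induced by Wnt signalling, the Wnt secretion gene Wls (2.15) and Dkk2 (2.77), and the falls were Fzd5 and Lgr5 (-1.83). Dkk2 differed by 4.26 within the replicate 1 arrays and 1.29 within the replicate 2 arrays (limma adjusted p = 0.394 after quantile normalization). The Wnt list median was 0.39 within the replicate 1 arrays and -0.03 within the replicate 2 arrays. The list no longer passed after quantile normalization (adjusted p = 0.108), with genes under the median level left out (adjusted p = 0.0835) or without labelled knockout replicate 1 (adjusted p = 0.924). Ciliary margin genes had 4 of 20 members higher, Wls, Bmp4, Mitf (1.41) and Cpxm2 (1.76), and 2 lower, Wfdc1 (-2.32) and Cdon. Adjusted over the list alone, 7 were higher and 3 lower (3 and 2 after quantile normalization). The list passed (median 0.26, camera adjusted p = 0.0102, adjusted p = 0.620 with an estimated correlation). That list did not pass with genes under the median level left out (adjusted p = 0.150), without control replicate 1 (adjusted p = 0.148) or without labelled knockout replicate 1 (adjusted p = 0.924), and Cpxm2 differed by 3.07 and 0.45 within the replicate 1 and replicate 2 arrays. Periocular mesenchyme genes rose in the same arrays, with a median of 1.40.

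Other signalling lists moved little. Notch pathway genes had 2 of 22 members lower, Dll4 and the target gene Hey1 (-1.40), and 0 higher, or 4 and 1 adjusted over the list alone. The list passed (median -0.19, camera adjusted p = 0.0332, adjusted p = 0.585 with an estimated correlation). It did not pass in 8 other settings at the preset correlation: quantile normalization (adjusted p = 0.0807), median centring (0.229), genes under the median level left out (0.0911), no intensity trend (0.0574), all probe sets (0.0619), the replicate number as a term (0.225), and without control replicate 1 (0.740) or labelled knockout replicate 2 (0.269). In the Hedgehog pathway 2 of 15 genes fell, the effector gene Gli1 (-1.82) and the co-receptor gene Cdon, and 0 rose. Adjusted over the list alone, 2 fell and 1 rose (0 and 0 after quantile normalization). The list did not pass (median -0.10, camera adjusted p = 0.417), but did without control replicate 2 (adjusted p = 0.0143) or labelled knockout replicate 1 (adjusted p = 0.000195). BMP pathway genes did not pass as a list (camera adjusted p = 0.850), with Bmp4 higher and Smad9 (-1.41) and Id1 lower among 23, and 1 rise and 2 falls adjusted over the list alone. The list's median of -0.10 and mean of 0.02 differed in sign. The 4 probe sets of Smad9 ranged from -1.41 to -0.08.

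Markers of several tissues that surround the neuroretina, led by periocular mesenchyme, rose in the labelled knockout arrays. Of 26 periocular mesenchyme genes, 13 rose and 0 fell (17 and 0 adjusted over the list alone, 0 and 0 after quantile normalization). The median was 1.40 (camera adjusted p = 1.82e-54, adjusted p = 0.522 with an estimated correlation). The matrix genes Col1a1 (3.33), Postn (3.11), Col3a1 (2.84) and Col1a2 (2.35) led them, and the list median was 2.60 within the replicate 1 arrays and 0.37 within the replicate 2 arrays. Without labelled knockout replicate 1 the mesenchyme median was 0.65, beside 0.20 over all genes. Retinal pigment epithelium genes rose in 9 of 27 members and fell in 0 (10 and 0 adjusted over the list alone, 1 and 0 after quantile normalization), among them the melanin synthesis genes Dct (2.32), Tyr (1.97) and Tyrp1 (1.47) and Gpnmb (1.80). The list median was 0.42 (camera adjusted p = 9.31e-15, adjusted p = 0.522 with an estimated correlation). Their medians were 0.99 within the replicate 1 arrays and 0.08 within the replicate 2 arrays, with 4.08 and 0.56 for Dct. The list median was 0.37 without labelled knockout replicate 1, beside 0.20 over all genes. The control arrays also differed, with Dct at 4.95 and 7.18 in control and 9.03 and 7.74 in labelled knockout replicates 1 and 2. After quantile normalization the list median of replicate 1 minus replicate 2 was -0.34 in control and 0.60 in labelled knockout arrays. The 3 probe sets of Tyr ranged from 0.96 to 2.69.

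Vascular genes rose as a list (median 0.63, camera adjusted p = 9.58e-07, adjusted p = 0.585 with an estimated correlation), with the endothelial receptor gene Tek (1.97) the 1 member past the gene threshold among 20. Extraocular muscle genes (median 0.53, camera adjusted p = 1.32e-07, adjusted p = 0.522 with an estimated correlation) had Actc1 (2.33) higher among 16. Surface ectoderm and cornea genes (median 0.43, camera adjusted p = 3.08e-05, adjusted p = 0.585 with an estimated correlation) had the keratin gene Krt5 (1.68) higher among 19. Adjusted over each list alone, 2 vascular, 3 muscle and 4 ectoderm genes rose, and 0 fell in any of these 3 lists, while after quantile normalization 0 passed. Without labelled knockout replicate 1 the 3 lists did not pass, at adjusted p of 0.0569, 0.536 and 0.536, and ectoderm genes did not with genes under the median level left out (0.114). List medians within the replicate 1 and replicate 2 arrays were 0.88 and 0.22 for vascular, 0.85 and 0.09 for muscle, and 0.84 and 0.16 for ectoderm genes. Actc1 differed by 3.89 and 0.77 and Krt5 by 3.20 and 0.16 within the replicate 1 and replicate 2 arrays. Macrophage and microglia genes lay above 0 in 19 of 19 members, with a median of 0.37 within the replicate 1 arrays and 0.44 within the replicate 2 arrays (camera adjusted p = 0.000102, adjusted p = 0.620 with an estimated correlation). The mean over these 19 members, 0.46, became 0.15 without control replicate 1 or labelled knockout replicate 2. Without control replicate 2 or labelled knockout replicate 1 it became 0.77. The median over all genes moved the same way, from -0.06 to -0.30 and -0.33 in the former fits and to 0.19 and 0.20 in the latter. Of the 19 macrophage and microglia genes, 0 passed the gene threshold on deposited values, over all genes or over the list alone (3 rose over the list alone after quantile normalization). Csf1r and Adgre1 differed by 0.97 and 1.03. Of 18 lens crystallin genes 0 passed, over all genes or over the list alone (median -0.12, camera adjusted p = 0.603), with values of 0.83 for Cryba1 and -0.59 for Cryaa. Of 11 erythroid genes 0 passed over all genes and 1 rose over the list alone (median 0.11, camera adjusted p = 0.0581). The erythroid list passed upward with genes under the 25th percentile (adjusted p = 0.0233) or the median of level left out (0.0319), after median centring (0.0378) and without control replicate 2 (0.00393). Its members Alas2 and Hbb-y differed by 1.30 (adjusted p = 0.0639) and 0.79 (adjusted p = 0.514).

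**Figure D2:**
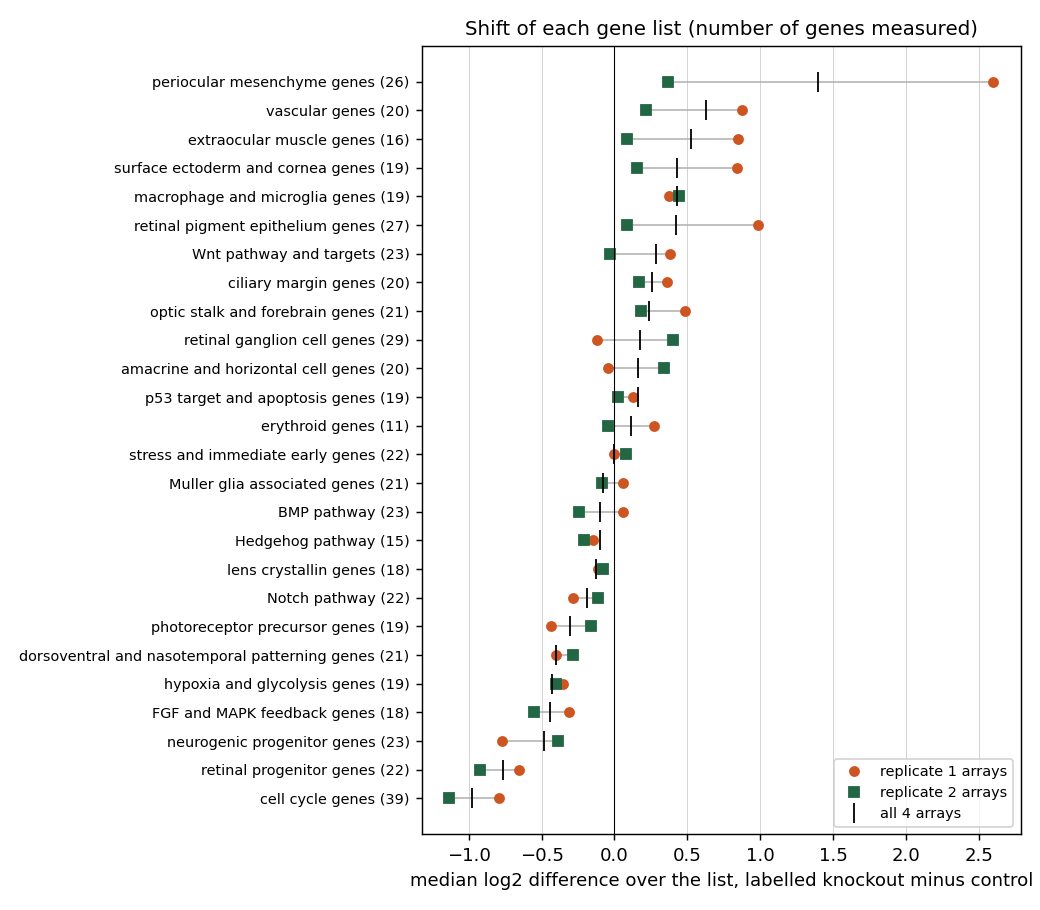
Median log2 difference, labelled knockout minus control (horizontal axis), of each of 26 gene lists, with the number of genes measured in parentheses, for the replicate 1 arrays (circles), the replicate 2 arrays (squares) and all 4 arrays (vertical bars). Periocular mesenchyme genes have the widest gap between replicate numbers, 2.60 against 0.37, and cell cycle genes lie lowest, at -0.98 over all arrays.

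Among stress-related lists, hypoxia and glycolysis genes lay below 0 in 18 of 19 members, with a median of -0.43, or -0.35 and -0.40 within the replicate 1 and replicate 2 arrays (camera adjusted p = 3.32e-05, adjusted p = 0.522 with an estimated correlation). The hypoxia-induced gene Ndrg1 (-2.02) was the 1 member that fell, over all genes and over the list alone, and 0 rose. Medians of mesenchyme, vascular and pigment epithelium genes in these arrays were 1.40, 0.63 and 0.42, or 0.37, 0.22 and 0.08 within the replicate 2 arrays. The hypoxia median was -0.21 without labelled knockout replicate 1, beside 0.20 over all genes. Of 19 p53 target and apoptosis genes, the kinase gene Plk2 (1.87) rose and 0 fell, over all genes and over the list alone (median 0.16, camera adjusted p = 0.142). That list passed upward after median centring (adjusted p = 0.0378) and with the replicate number as a term (0.0474). In the list of 22 stress and immediate early genes 0 passed, over all genes or over the list alone (camera adjusted p = 0.600). The median of -0.01 and mean of 0.07 differed in sign, and Hmox1 and Ier2 differed by 0.82 and -0.55. In total 17 of 27 lists passed at the preset correlation, 15 after quantile normalization and 0 with an estimated correlation.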

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

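Of the tests given here, those of a further mesenchymal list and a further forebrain list were set before their results were seen, and the others were chosen only after the result was seen, those of array level and retinal share after earlier forms of them had been run.

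Transcript clusters outside the gene comparison were also tested: 99 of 84402 clusters unnamed here passed limma's adjusted p of 0.05 on deposited values, 68 higher and 31 lower in the labelled knockout arrays. At an unadjusted p under 0.05 there were 1144, fewer than the 4220.1 expected by chance, on a scale where 36.0% of simulated gene calls were false. The simulation did not include these clusters. After quantile normalization 0 passed at an adjusted p of 0.05 or 0.10, and of 2290 clusters with several gene symbols 2 passed on deposited values.

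Periocular mesenchyme genes had the largest pooled list median, 1.40, but 2.60 within the replicate 1 arrays and 0.37 within the replicate 2 arrays. More mesenchymal RNA in the labelled knockout arrays is a candidate explanation: a further list of 35 mesenchymal genes, none in a fixed list, had a median of 0.78 after quantile normalization (95% bootstrap interval over genes 0.47 to 1.19), carried by replicate 1 (deposited medians 1.37 and 0.15 by replicate number; camera adjusted p = 3.82e-08 after quantile normalization, adjusted p = 0.327 with an estimated correlation). A lower share of retinal cells would raise markers of other tissues alike, but among members above the 75th percentile of signal in both control arrays, after quantile normalization, 8 mesenchyme genes lay above 11 lens, erythroid, vascular and macrophage genes by 1.31 log2 units in median (95% bootstrap interval over genes 0.44 to 2.68). Within the replicate 1 arrays, which carry most of the pattern, the gap was 2.29 (1.37 to 3.95), and within the replicate 2 arrays it was 0.59 (-0.63 to 1.46). The genes compared thus did not rise alike in replicate 1, but each of these gaps rests on 1 array per group. The comparison also leaves out pigment epithelium, muscle and ectoderm genes, whose deposited medians within the replicate 1 arrays were 0.99, 0.85 and 0.84. A lower share of retinal cells is therefore not set aside for either replicate number. A change of tissue around or within the retina with the Lhx2 genotype stays open, and was not tested.

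Sim1, Lhx5, Rspo3 and 4 other forebrain genes rose, and after quantile normalization list members at 1 or above in the replicate 1 arrays had a median of 4.56 in replicate 2 (95% bootstrap interval 2.95 to 4.79), those chosen in replicate 2 one of 2.66 in replicate 1 (0.69 to 3.63, its lower bound under the bar of 1 in an earlier form of the level test). The level difference between arrays followed the replicate number, which both groups share, so it largely cancels in the group difference. A mean kept after rescaling therefore does not test it as a cause. Over the 21 measured members of that list the mean was 1.06 on deposited values and 1.07 after quantile normalization (95% bootstrap interval over genes 0.21 to 1.97). The deposited mean was 0.60 without labelled knockout replicate 2 and 1.52 without labelled knockout replicate 1. The median over all genes was -0.33 and 0.20 in those fits. Camera passed after quantile normalization (adjusted p = 0.0149) and median centring (2.24e-05), though not with an estimated correlation (0.522 on deposited values). Carry-over of forebrain tissue in general remains undecided: a further list of 37 regional forebrain genes had a median of 0.0747 after quantile normalization (95% bootstrap interval -0.02 to 0.34), with 22 of 37 (59.5%) above 0 and Trh 1.43 higher on deposited values. Camera placed that list upward after quantile normalization (adjusted p = 0.00373, 0.273 with an estimated correlation), so carry-over is neither shown nor set aside. A change of retinal cells toward forebrain gene expression with the Lhx2 genotype is a further hypothesis that these arrays did not test.

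The count of called genes moved with the scale of the arrays. The level difference between replicate numbers may enter the residual spread of every gene and make that spread look alike: limma's prior degrees of freedom were infinite on deposited values and 2.73 after quantile normalization, while the median residual SD went from 0.379 to 0.151. Of the 3 splits of the 4 arrays into pairs, 2 gave as many called genes on deposited values, 415 for genotype and 7384 for replicate number, a many times higher count that points to a structure by replicate number; the crossed split gave 0. With 3 splits no share under 0.05 can be reached. After quantile normalization, at an adjusted p of 0.10, the genotype split gave 86 genes and the other splits 0 each, while at an unadjusted p under 0.05 they gave 2318 for genotype, 1737 for replicate number and 227 for the crossed split, so structure by replicate number remains.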

How the results depend on the processing

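Quantile normalization at an adjusted p of 0.10, quantile normalization with the replicate block and quantile normalization over all transcript clusters were chosen after seeing the data. The cause of a change was not tested except where a setting's construction (fewer genes, fewer arrays) gives it. Against 415 genes called by limma, 272 were called with genes under the 25th percentile of level left out and 19 with genes under the median left out. Quantile normalization gave 0 (86 at an adjusted p of 0.10) and 0 over all transcript clusters. Median centring gave 118, eBayes without trend 271, no variance moderation 0, and an unadjusted p under 0.01 with at least 1.5-fold 756. Robust eBayes (373), array weights (415), all probe sets (358), their mean (336), an adjusted p of 0.10 (494) and a 1.5-fold minimum (415) stayed within 1.5 times. With 1 array left out the count was 127 to 285, and the median difference over all genes went from -0.06 to between -0.33 and 0.20. That median was -0.14 after median centring and -0.02 after quantile normalization.

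Replicate numbers are shared by the groups, and same-numbered deviations correlated across genes at 0.479 (0.456 after quantile normalization), but what the numbers stand for is not given in the sources used here. With the replicate number as a block limma called 0 genes, 3513 at an unadjusted p under 0.05 and 415 at an adjusted p under 0.10, of which 238 are among the 415 called without it; quantile normalization with the block gave 0 at 0.05 and 255 at 0.10. With the block 17 lists passed, not the same ones: Notch genes no longer passed (adjusted p = 0.225) and p53 target genes did (0.0474).

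Lists past the threshold numbered 17, and 0 with an estimated correlation or with fry in 1 direction (10 in fry's mixed test of either direction); with 1 array left out, 14 to 19 passed. Camera has no counterpart for robust or absent moderation, so lists were not run there. The Lhx2 difference became -0.0631 after median centring and ran from -0.0488 to 0.0809 with 1 array left out. Among lists that did not pass, the test's direction turned as follows, given as mean log2 difference. BMP genes were at 0.00410 with the 25th percentile filter, -0.0689 with the median filter, 0.01003 after quantile normalization, 0.0159 with all probe sets, and -0.17 to 0.20 with 1 array left out. Amacrine and horizontal cell genes were at -0.13 with the median filter, 0.0345 with fry, and -0.29 to 0.35 with 1 array left out. With all probe sets that list passed downward (camera adjusted p = 0.00798), and the mean was not taken again there. Muller glia genes were at -0.00274 with the median filter. Hedgehog genes were at -0.20 after median centring, -0.12 with the block and -0.29 to 0.0467 with 1 array left out. With 1 array left out, ganglion cell genes ran from -0.33 to 0.48, lens genes from -0.35 to 0.14 and the gene Cryaa from -1.32 to 0.14. Of the 99 named genes with a call, 99 lost it after quantile normalization and 54 after median centring, none changing sign; 54, 50, 47 and 29 lost it without control 1, control 2, labelled knockout 1 and labelled knockout 2.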

Other observations

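The families in this part, 26 defined by gene symbol, were chosen after the data were seen, as were the genes named with them; camera p-values are adjusted over the 26. Protocadherins, cell adhesion molecules of neurons, were higher: 8 of 35 rose and 0 fell, and 32 lay above 0 after quantile normalization. The median was 1.04, or 0.61 and 1.29 within the replicate 1 and replicate 2 arrays (camera adjusted p = 3.29e-24, 1.20e-14 after quantile normalization, adjusted p = 0.512 with an estimated correlation). Pcdh10 rose by 1.64 and Pcdh18 by 1.53, and the others that rose belong to the clustered beta group, whose similar sequences make probes shared between members possible. Semaphorins and their plexin receptors, axon guidance molecules, had 3 of 30 members higher, Sema3d (2.39), Sema5a (1.88) and Plxna4 (1.75), and 1 lower, Sema4d (-1.39), with a median of 0.40 (camera adjusted p = 5.26e-07, adjusted p = 0.512 with an estimated correlation). Sema5a varied widely, with an SD of 1.44 in control and 1.09 in labelled knockout arrays (limma adjusted p = 0.583 after quantile normalization). Of 16 glutamate receptor subunit genes Gria2 (1.96) rose and the median was 0.39 (camera adjusted p = 0.000299, adjusted p = 0.692 with an estimated correlation). These medians rose in arrays whose mesenchyme medians were 2.60 and 0.37 by replicate number.

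Families of DNA replication and mitosis lay lower, some of whose members also stand in the fixed cell cycle list. Replication histones had 3 of 20 members lower, H1f5 (-1.68), H4c14 (-1.66) and H1f3 (-1.28), and a median of -0.60 (camera adjusted p = 1.88e-09, adjusted p = 0.512 with an estimated correlation). Among 22 MCM and origin licensing genes, Mcm10 (-1.22) fell and the median was -0.77 (camera adjusted p = 4.94e-12, adjusted p = 0.512 with an estimated correlation). Kinetochore and centromere genes had Nuf2 (-1.67) and Ndc80 (-1.22) lower among 29 and a median of -0.79 (camera adjusted p = 1.69e-13, adjusted p = 0.512 with an estimated correlation). Nuf2 varied widely, with an SD of 1.40 in control and 1.88 in labelled knockout arrays (limma adjusted p = 0.604 after quantile normalization). Complex I and proteasome subunits lay near 0, with medians of -0.04 over 44 genes and -0.05 over 36, and 0 of them passed. Cytosolic ribosomal protein genes lay lower: 5 of 60 were above 0 after quantile normalization, Rps18 and Rpl32l fell, and the median was -0.26, or -0.12 and -0.39 within the replicate 1 and replicate 2 arrays (camera adjusted p = 0.00161, 0.0452 after quantile normalization, adjusted p = 0.929 with an estimated correlation). Each of these medians kept its sign after quantile normalization. In the same arrays mesenchyme, vascular and pigment epithelium genes had medians of 1.40, 0.63 and 0.42, or 0.37, 0.22 and 0.08 within the replicate 2 arrays.

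Sex-linked genes were given as values only. Xist had log2 signals of 9.68 and 9.95 in control replicates 1 and 2 and 10.7 and 10.3 in labelled knockout replicates 1 and 2, and the Y-linked Eif2s3y had 5.93, 6.80, 5.40 and 6.47 in the same order. Kdm5d had 6.24 and 6.24 in control and 5.34 and 6.50 in labelled knockout arrays, and Uty 4.66 and 4.61 against 3.66 and 3.66. Xist, Eif2s3y and Kdm5d lay above the 75th percentile of all transcript clusters on every array, as RNA of both sexes would. Uty lay below it in the labelled knockout arrays. No array of 1 known sex sets the background of these genes, so pooling of embryos is not settled. Differences of 0.68 for Xist and -0.97 for Uty did not pass limma's threshold (adjusted p = 1.00 and 0.681).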
